A study of Mus musculus with 8 samples.

How the data were processed

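The data are 2-colour Agilent 4x44K mouse expression arrays of striatal RNA from adult female mice, 4 wildtype and 4 Brd2 heterozygous samples. Mice came from crosses of heterozygous parents after repeated backcrossing to C57Bl/6J, and genotypes were set by PCR across the gene-trap junction, per the labels' protocols. RNA was amplified and labelled with Cy3 or Cy5, and 2 differently labelled replicates of the same genotype shared each of 4 arrays, per the labels and the series' design text. The scanner files of both samples of an array were byte-identical, and each sample was read from its own channel. The design text calls the replicates biological; whether each sample was a single animal is not given in the sources used here, so p-values measure the spread between these samples.

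Spot intensities (mean and median brightness and local background, linear scale) were extracted with Agilent Feature Extraction 10.7.3.1 from 1 scan of array design 026655, per the file headers. The same files hold processed intensities that the scanner software had background-subtracted, spatially detrended and dye-normalized, per the file headers. The deposited value table of the series holds, for each sample, a ratio of the background-subtracted median intensity of a spot to the median of its own column. This was found from the values: every listed spot was matched within a relative tolerance of 0.0001, and each column has a median of 1. Its scale is therefore known, it is not log-transformed, and it holds no centring of genes and no ratio between samples. In Cy5, 2167 to 3629 spots per sample were left empty there, none above 2 times its local background. In Cy3, where negative control spots measured 244 to 261 against a median spot intensity of 288 to 362, such a scale depends strongly on nonspecific signal. The table served as an alternative only.

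Mean and background-median intensities were corrected with normexp (offset 50), normalized by loess within arrays and by Aquantile between arrays in limma 3.58.1 (R 4.3.3, statmod 1.5.0, data.table version 1.17.8), and split into single-channel log2 values. There were 43020 spots of 39429 probes; 1377 control spots were left out after background correction. Spots marked as outliers in the sample's own channel (230 to 978 per sample) were left out, no spot was saturated, and replicate spots of a probe were averaged. A probe was kept if it was well above background, by the scanner's own call, in at least 4 of the 8 samples (25336 probes). Gene names came from the RefSeq gene table of assembly GRCm38.p6, by accession for 27234 probes and by a current symbol for 3576. The remaining 8619 kept the file's name, and 8050 of these had no symbol. The brightest probe represented each gene, which left 19828 genes, 16060 of them with a symbol. Probe coordinates are those of the files (mm9); no genome sequence or annotation of that build was used.

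Genes were tested with limma's lmFit and eBayes with genotype and dye as fixed effects and the shared array as a random block (consensus correlation 0.0076, prior degrees of freedom 2.91), with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. Each gene chosen by the naming rule was well above background in at least 2 samples per genotype, so no fold was given as a bound. All arrays were on 1 slide with 1 scan, so neither could be tested as a batch. Each array held 1 genotype, with 2 arrays per genotype, so effects of single arrays cannot be fully told apart from genotype. The 27 gene lists were fixed before the data were examined. They were tested with camera on values and design whitened by the array correlation (preset inter-gene correlation 0.01), adjusted over the 27 lists; only genes with values in all samples (18594) entered. An estimated correlation and fry, which asks whether a list's genes move on balance in one direction without comparing them with other genes, served as alternatives. Brd2 was compared by an exact two-sided permutation test as well.

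The genes named were set by a rule written before the data were examined: Brd2; the 12 largest changes in each direction among genes past the threshold with non-overlapping groups, filled with the smallest p in that direction where fewer passed; the 2 members with the smallest p of each list; and Gad1, Gad2, Pvalb, Drd1, Drd2, Penk, Pdyn, Tac1, Slc17a7, Mbp and Ttr. A further gene that this rule picks is not reported here. Stx1a, Syt7, Sv2c, Kcna5, Tbr1, Neurod2, Emx1, Hbb-bt, Btbd9, Hcrt, Avp and Prkcd were named after their values were seen. Alternatives covered the background correction, the normalization, the value table, the filter on dim probes, the choice of probe, the array and replicate blocks, the dye, the variance model, the threshold and leaving out each sample. Figures were drawn with matplotlib 3.10.9.

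The fit was tested on simulated data with the levels, dye effects and spreads of the 19828 genes. Of 100 genes changed 2-fold it recovered 78%, and of 100 changed 4-fold 97%, with 13 false calls in all. With no change it called 0 genes, and a list shifted by 0.4 was called by camera with either correlation and by fry, with no other list called. The simulated genes were independent of each other, which real genes are not. All changed genes were also planted in the same simulated data, which eases the adjusted threshold. With fewer changed genes the adjustment is stricter, so these shares do not give the chance of finding a 2-fold change here.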

Results

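Gene expression was measured in the striatum of adult female C57Bl/6J mice that carried either 2 intact copies of Brd2 or 1 intact copy and 1 gene-trap insertion. Brd2 encodes a bromodomain protein of the BET family, which binds acetylated histones and takes part in transcription. The tissue label also names the prefrontal cortex, and the sample descriptions name the striatum alone. There were 4 wildtype and 4 heterozygous samples, hybridised in pairs of one genotype to 4 arrays of a single slide. Replicates 1 and 3 of each genotype carried the dye Cy3 and replicates 2 and 4 carried Cy5. The share of spots well above background was lower in Cy3, at 43.6% and 47.6% in wildtype and 47.5% and 37.7% in heterozygous samples. It was 65.9% and 68.9% in the wildtype and 74.7% and 75.5% in the heterozygous Cy5 samples. The lowest share, 37.7%, belonged to the library labelled heterozygous replicate 3. The number of samples limits the precision of every difference below. Males, which the study's title implies were also of interest, were not analysed here.

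The single comparison of the design asked how loss of 1 Brd2 copy changes striatal expression in females. Unless stated otherwise, differences are heterozygous minus wildtype on the log2 scale, with the standard error (SE) of the limma fit and 4 samples per genotype. Spots marked as outliers left 2 wildtype values for Clptm1 and Tac1, 3 for Vps11, Vamp1, Pde10a and Rpl13, 2 heterozygous values for Hexim2, and 3 for Bag5, Gad2 and Ier5. SDs of genes other than Brd2 are after removal of the dye effect.

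Brd2 itself was lower in all 4 heterozygous samples than in any wildtype sample. Its 3′ probe (A_55_P1958678, chromosome 17, 34248982 to 34249041, minus strand, mm9 coordinates of the array files, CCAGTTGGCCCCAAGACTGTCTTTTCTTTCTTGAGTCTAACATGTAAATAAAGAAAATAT) starts at base 4590 of its transcript. It averaged 12.86 ± 0.22 (SD, n = 4) in wildtype and 12 ± 0.39 (SD, n = 4) in heterozygous samples on the log2 scale, so the heterozygous mean was 55.4% of the wildtype mean. The difference exceeded the spread between replicates in an exact two-sided permutation test of these values (p = 0.0286, the smallest that 4 against 4 samples can give). That test permuted samples singly, without regard to dye or shared array, and only 3 splits of the 8 samples keep arrays whole. In the limma fit over all genes the Brd2 difference was -0.85 (SE 0.193) and missed the threshold after Benjamini-Hochberg adjustment (adjusted p = 0.431). Heterozygous replicates 1, 2 and 4 measured 11.92, 11.83 and 11.70. The library labelled heterozygous replicate 3 measured 12.57, or 81.8% of the wildtype mean, next to the lowest wildtype value of 12.64. Its label is therefore in doubt, and every direction below includes it unless stated. Without it the remaining 3 heterozygous samples averaged 48.6% of the wildtype mean. With the scanner software's processed signals it stood at 92.2% of the wildtype mean and the exact permutation p was 0.0571; in the deposited value table, where Brd2 lay lower in Cy3 (log2 ratios 4.2 and 4.21 in wildtype) than in Cy5 (5.2 and 5.09), it measured 3.17, next to the other heterozygous Cy3 sample at 3.24, and the exact permutation p, with the dye not removed, was 0.114. The second Brd2 probe (A_55_P1953545, chromosome 17, 34255967 to 34256026) lay near background. It was well above background in 2 wildtype and 3 heterozygous samples, and averaged 8 ± 0.23 and 8.29 ± 0.26 (SD, n = 4). The mean of both probes gave a difference of -0.28. The position of the gene-trap insertion was not given in the sources used here, so which transcripts either probe reads from the trapped copy is unknown.

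**Figure D1:**
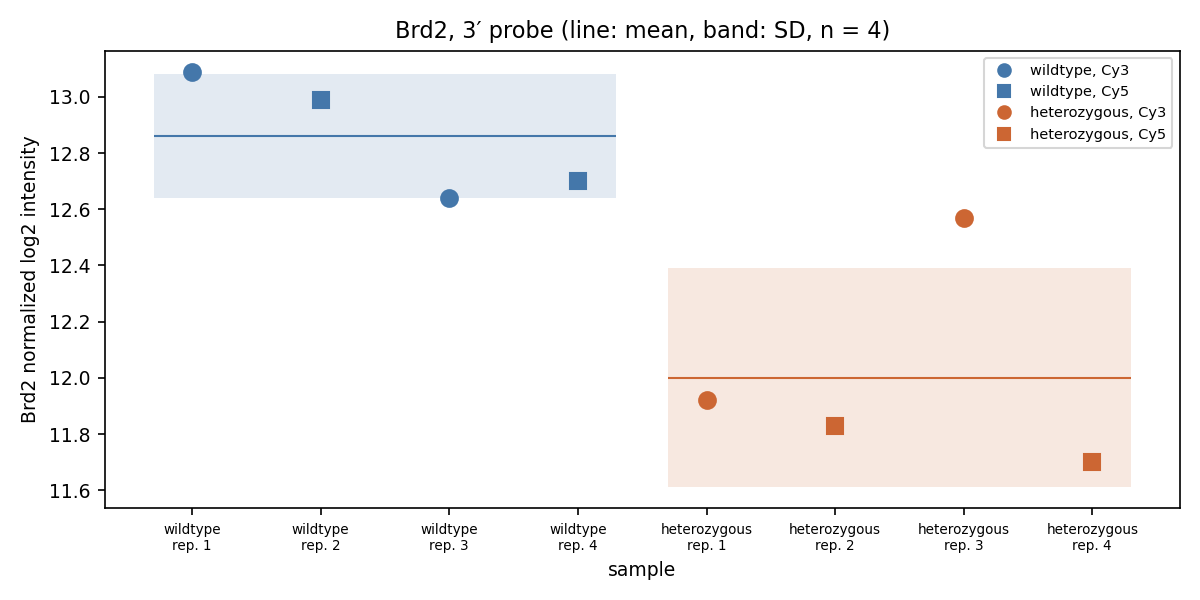
Normalized log2 intensity of the Brd2 3′ probe (vertical axis) in each of the 8 samples (horizontal axis), coloured by genotype, with circles for Cy3 and squares for Cy5. Lines are genotype means and bands are the SD of 4 samples; heterozygous replicate 3, at 12.57, lies next to the lowest wildtype sample, at 12.64, and the other heterozygous samples lie between 11.70 and 11.92.

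No gene other than Brd2 was singled out by the design, and none of the 19828 genes tested passed the threshold in limma (0 higher and 0 lower, smallest adjusted p = 0.133). At an unadjusted p under 0.05 there were 1726 genes, 771 higher and 955 lower in heterozygous samples, where 991 would be expected by chance. After removal of the dye effect, the 4 values of one genotype all lay on one side of the 4 of the other for 8.7% of the genes measured in every sample. The chance share of 2.86% is that of values without such removal, so the excess over it cannot be read as a genotype effect. The genes below had the smallest p in each direction and all missed the threshold.

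Among lower genes the smallest p belonged to Ido1, an enzyme that starts tryptophan breakdown along the kynurenine pathway. Ido1 averaged 9.77 ± 0.14 (SD, n = 4) in wildtype and 8.63 ± 0.06 (SD, n = 4) in heterozygous samples, a difference of -1.15 (SE 0.110) in 4 of 4 samples. The difference was -0.94 (SE 0.137) for the keratin gene Krt9, -1.19 (SE 0.186) for the retinoid isomerase gene Rpe65, and -0.75 (SE 0.122) for Camk1g, a calcium/calmodulin-dependent kinase. It was -0.71 (SE 0.109) for the purine nucleoside phosphorylase gene Pnp2 and -0.57 (SE 0.103) for the growth factor gene Hbegf. Mzf1, Ifi27l2b, Upb1, H4c3, Bag5 and Smc5 completed the 12 genes with differences between -0.67 and -0.50. Ido1 and Rpe65 were well above background in 4 wildtype and 3 heterozygous samples, H4c3 in 3 and 2, and Ifi27l2b in 2 per genotype. Second probes of Smc5 and Ifi27l2b, both dim (7.46 to 8.26 and 6.76 to 7.69), measured -0.01 (SE 0.155) and -0.08 (SE 0.163). A brighter second Bag5 probe (10.35 to 11.34) measured -0.28 (SE 0.156).

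Among higher genes the smallest p belonged to Frzb, a secreted Wnt antagonist, with a difference of 0.81 (SE 0.099). It was well above background in 2 wildtype and 3 heterozygous samples. The serotonin receptor gene Htr1a differed by 0.70 (SE 0.094) and Slc30a3, the zinc transporter of synaptic vesicles, by 0.76 (SE 0.105); each was well above background in only 2 samples per genotype. S100a10 differed by 0.79 (SE 0.116), the postsynaptic scaffold gene Dlgap1 by 0.84 (SE 0.130), and the potassium channel gene Kcnc4 by 0.88 (SE 0.143). Adgra1, an adhesion receptor gene, had the largest difference of the 12, at 1.17 (SE 0.182), followed by Clptm1 at 1.04 (SE 0.131) and Vps11 at 0.98 (SE 0.151). Cables2, Myoc and Mpi lay between 0.60 and 0.70, and Myoc was well above background in only 2 samples per genotype. The 2 further Dlgap1 probes measured 0.33 (SE 0.170) and 0.39 (SE 0.130).

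**Figure D2:**
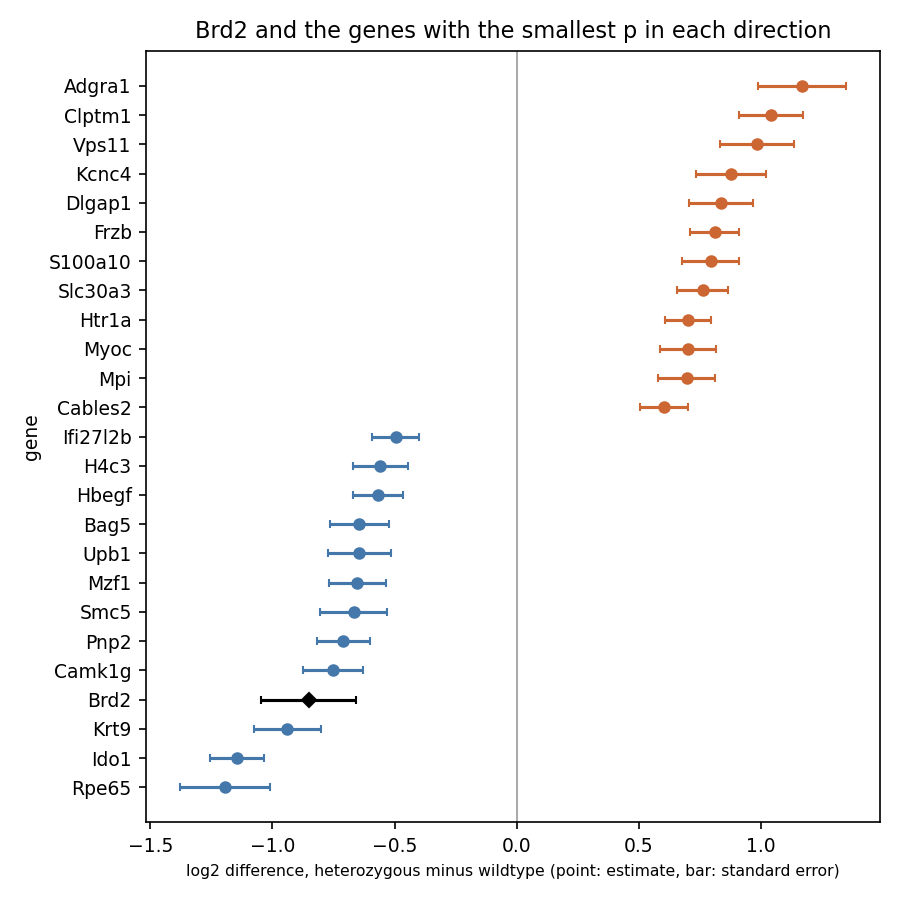
Log2 difference, heterozygous minus wildtype (horizontal axis), of Brd2 (diamond) and of the 12 genes with the smallest p in each direction (vertical axis). Points are limma estimates and bars their standard errors from 4 samples per genotype, except 2 wildtype samples for Clptm1, 3 wildtype samples for Vps11 and 3 heterozygous samples for Bag5; estimates run from -1.19 for Rpe65 to 1.17 for Adgra1, and none passed the threshold after adjustment.

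Markers of striatal projection neurons, the main neurons of this tissue, were lower in heterozygous samples. Of 32 tested members 31 had a negative difference, with a median of -0.36, and the list passed the threshold in camera with a preset inter-gene correlation (adjusted p = 2.59e-05). With an estimated correlation it did not (adjusted p = 0.84). No member passed over all genes, and Ido1 and Foxp1 passed when adjusted over the list alone. Foxp1, a transcription factor gene, measured 14.25 ± 0.06 in wildtype and 13.50 ± 0.29 in heterozygous samples (SD, n = 4), a difference of -0.75 (SE 0.155). Further Foxp1 probes measured -0.46 (SE 0.241), -0.29 (SE 0.157) and, at a dim probe (7.64 to 8.22), 0.06 (SE 0.142). Pde10a, which encodes a phosphodiesterase abundant in these neurons, differed by -1.10 (SE 0.376). Tac1 differed by -0.73 (SE 0.387), Drd1 by -0.53 (SE 0.348), Pdyn by -0.50 (SE 0.241), Penk by -0.37 (SE 0.312) and Drd2 by -0.28 (SE 0.299), and none of these passed. Relative to the wildtype mean the list's level was -0.84 in the library labelled heterozygous replicate 3, -0.60 in replicate 2, -0.15 in replicate 4 and 0.00 in replicate 1. Without replicate 3 the median was -0.16 and the call ended (adjusted p = 0.104), and the differences were then -0.63 for Pde10a, -0.43 for Tac1, -0.16 for Drd1, -0.01 for Penk and 0.02 for Drd2. Pdyn differed by -0.26 without heterozygous replicate 2 and by 0.09 (SE 0.207) at a second, dim probe. The dopamine signalling list, which shares several of these genes, had a median of -0.25 and missed the threshold (adjusted p = 0.143), which it passed in 4 of 28 alternatives; the median was -0.12 without the library labelled heterozygous replicate 3 and -0.16 without heterozygous replicate 2. Its members with the smallest p were Pde10a and Kcnj6, the latter with a difference of 0.26 (SE 0.093) and well above background in 2 samples per genotype.

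Markers of cortical excitatory neurons were higher as a list. The median over 28 tested members was 0.18 and the mean 0.42, 18 members had a positive difference, and the list passed in camera with the preset correlation (adjusted p = 0.0208). With an estimated correlation it did not (adjusted p = 0.84). Slc17a7, the vesicular glutamate transporter of cortical neurons, differed by 2.15 (SE 0.406) and was well above background in 2 wildtype and 4 heterozygous samples. The neurite growth gene Nrn1 differed by 1.81 (SE 0.388), and the transcription factor genes Tbr1, Neurod2 and Emx1 by 1.92 (SE 0.515), 1.43 (SE 0.394) and 1.17 (SE 0.257). These 5 members passed when adjusted over the list alone, and none did over all genes. The list's level above the wildtype mean was 0.77, 0.56, 0.22 and 0.11 in heterozygous replicates 1 to 4, and 0.29 in wildtype replicate 2. The call ended without wildtype replicate 3 (median 0.19, adjusted p = 0.0717), wildtype replicate 4 (0.08, adjusted p = 0.118) or heterozygous replicate 2 (0.005, adjusted p = 0.296), without the dye covariate (adjusted p = 0.0752), and over the 16 members well above background in all 8 samples (-0.02, adjusted p = 0.601). The last setting leaves out 12 members, among them Slc17a7 and others low in wildtype, whose median was 0.50. The median was 0.07 without heterozygous replicate 1 and 0.29 without replicate 4, where the call held, as it did without the library labelled heterozygous replicate 3 (adjusted p = 0.0305). Among the glutamate signalling genes, Dlgap1, Slc17a7 and Slc17a6 passed when adjusted over the list alone. Slc17a6, a second vesicular glutamate transporter, differed by 1.14 (SE 0.233) and was well above background in 2 wildtype and 4 heterozygous samples. The glutamate list had a median of 0.05 over 45 members and missed the threshold (adjusted p = 0.0536), which it passed in 6 of 28 alternatives. Its median ranged from -0.003 to 0.155 over the alternatives and was 0.01 without the library labelled heterozygous replicate 3.

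Genes of synaptic vesicle release were higher as a list as well. Of 50 members 32 had a positive difference, with a median of 0.14 (adjusted p = 0.0142 with the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.84). Vamp1, a vesicle SNARE gene, differed by 1.45 (SE 0.284), the syntaxin gene Stx1a by 1.10 (SE 0.248), Doc2a by 0.81 (SE 0.173) and the synaptotagmin gene Syt7 by 0.55 (SE 0.129). These 4 passed when adjusted over the list alone, and none did over all genes. Sv2c went the other way, at -1.96 (SE 0.557), a mean over dyes that differed. Its difference was -3.50 in the Cy5 samples alone, and its Cy3 values lay closer together between genotypes. The list's call ended without wildtype replicate 3 (median 0.07, adjusted p = 0.0535), wildtype replicate 4 (0.05, adjusted p = 0.102), heterozygous replicate 1 (0.03, adjusted p = 0.0758) or heterozygous replicate 4 (0.075, adjusted p = 0.068). Without heterozygous replicate 2 it held with a median of 0.09. It also ended with the deposited value table (0.01, adjusted p = 0.185), without the dye covariate (adjusted p = 0.055), with probes well above background in all 8 samples (adjusted p = 0.0741) and in the Cy3 samples alone (adjusted p = 0.0996). The list's level above the wildtype mean was 0.27, 0.16, -0.02 and 0.13 in heterozygous replicates 1 to 4, where that of the cortical markers was 0.77, 0.56, 0.22 and 0.11. With the cortical level as a covariate, a setting chosen after seeing the data, the median was 0.00 (adjusted p = 0.643). That level itself differed between genotypes, so the covariate takes out part of any genotype difference and cannot tell causes apart. The voltage-gated channel list missed the threshold (median 0.03, adjusted p = 0.128) and passed it in 2 of 28 alternatives. Of its members 7 passed when adjusted over the list alone in both directions, among them Kcnc4 and Kcnc2, at 0.97 (SE 0.181), and Kcna5 at -0.75 (SE 0.158).

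**Figure D3:**
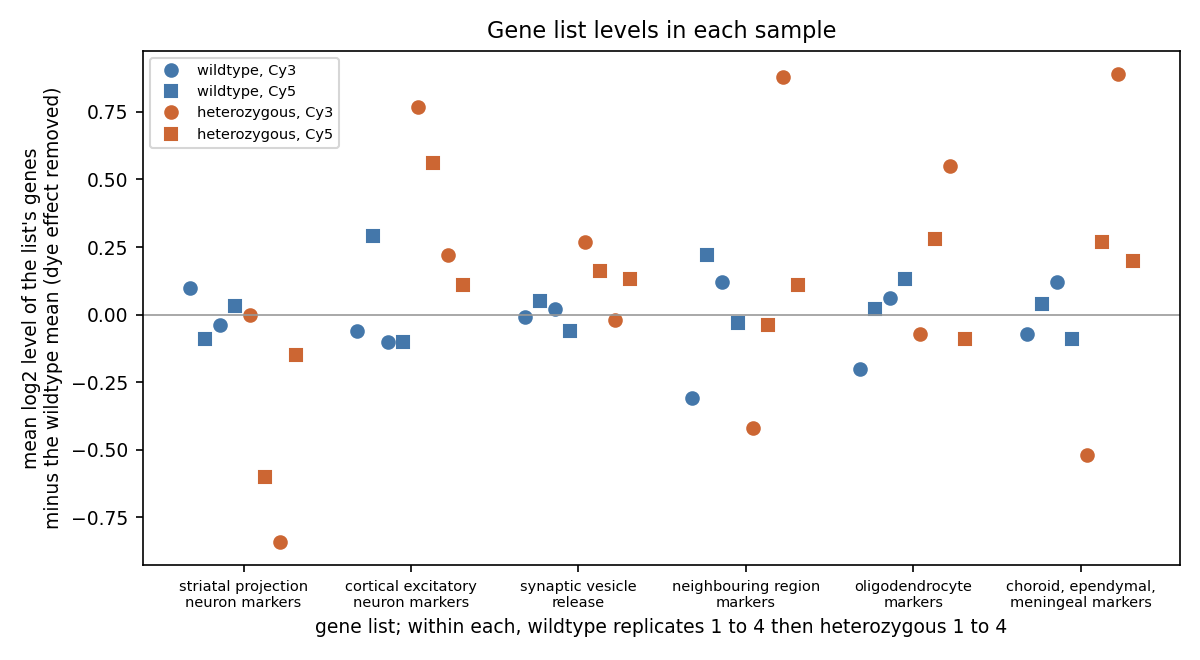
Mean log2 level of 6 gene lists in each sample, relative to the wildtype mean and with the dye effect removed (vertical axis), coloured by genotype, with circles for Cy3 and squares for Cy5; each point is 1 sample. Heterozygous replicate 3 lies lowest for striatal projection neuron markers, at -0.84, and highest for neighbouring-region markers, at 0.88, and for choroid, ependymal and meningeal markers, at 0.89.

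The other transmitter lists did not pass, and of these the neuropeptide list alone passed in any alternative (3 of 28). GABA signalling had a median of -0.01 (adjusted p = 0.96), with Gabra4, a GABA-A receptor subunit gene, at -0.57 (SE 0.164) and the transporter gene Slc6a13 at 0.82 (SE 0.262). Slc6a13 is also among the choroid, ependymal and meningeal markers. The GABA-synthesis gene Gad2 differed by -0.24 (SE 0.167), or by -0.07 without the library labelled heterozygous replicate 3, and Gad1 by 0.07 (SE 0.255), with the opposite sign in 8 of 26 alternative settings, among them both scalings of the processed signals and the value table. Acetylcholine signalling had a median of -0.07 (adjusted p = 0.824), and its choline transporter gene Slc5a7 differed by -0.67 (SE 0.198) and its receptor gene Chrna7 by -0.17 (SE 0.093). Chrna7 was well above background in only 2 samples per genotype. Serotonin signalling had a median of 0.03 (adjusted p = 0.43), with Htr1a passing when adjusted over the list alone and Htr7 at 0.40 (SE 0.164). Neuropeptides and opioid receptors had a median of 0.10 (adjusted p = 0.104), with Adcyap1 at 0.85 (SE 0.187) and Vip at 0.96 (SE 0.247). Over the alternatives the median ranged from 0.05 to 0.28, Adcyap1 from 0.64 to 1.54 and Vip from 0.57 to 1.56. Both genes were well above background in 2 wildtype and 3 heterozygous samples. Striatal interneuron markers had a median of -0.06 and a mean of 0.06 (adjusted p = 0.96). Pvalb, a marker of fast-spiking interneurons, differed by 1.58 (SE 0.658), with 15.10 in the library labelled heterozygous replicate 3 and 12.30 to 13.72 in the other heterozygous samples, and by 0.80 without that library.

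No list of non-neuronal or neighbouring-region markers passed in the planned comparison, and several moved with the library labelled heterozygous replicate 3. Of 28 alternatives, choroid markers passed in 9, oligodendrocyte markers in 5, neighbouring-region markers in 2, and precursor and progenitor markers in 1 each, all with a higher level in heterozygous samples, and blood cell markers in 11 with a lower level. Choroid plexus, ependymal and meningeal markers had a median of 0.28 (adjusted p = 0.0777), with Igfbp2 at 1.42 (SE 0.439) and Ptgds at 0.70 (SE 0.204). Without that library the median was -0.045 and Igfbp2 differed by 0.91; without heterozygous replicate 1 the list passed (median 0.36, adjusted p = 5.11e-06). Ttr, an abundant choroid plexus transcript, measured 16.29 there, 11.52 to 13.02 in the other heterozygous samples and 11.53 to 14.15 in wildtype. Markers of the thalamus, septum, pallidum and hypothalamus had a median of 0.07 (adjusted p = 0.286), and -0.03 without that library. Over the alternatives this median ranged from -0.03 to 0.35. Rora differed by 0.55 (SE 0.165). Slc17a6, which is on this list too, differed by 1.14 (SE 0.233), and by 0.92 to 1.34 with 1 sample left out. It alone passed when adjusted over this list. Oligodendrocyte markers had a median of 0.15 (adjusted p = 0.096), and 0.01 without the library labelled heterozygous replicate 3. Their median ranged from -0.004 to 0.336 over the alternatives. Mbp, the myelin basic protein gene, went against that list at -0.57 (SE 0.156), and at -0.23 (SE 0.142) and -0.305 (SE 0.128) at further probes. Ermn differed by 0.84 (SE 0.390), with 14.04 in that library and 12.26 to 12.42 in the other heterozygous samples. It differed by 0.37 without that library and by 0.14 (SE 0.133) at a second probe. Oligodendrocyte precursor markers (median 0.14, adjusted p = 0.286), astrocyte markers (-0.01, 0.96), microglia and macrophage markers (-0.08, 0.811) and endothelial and mural cell markers (0.04, 0.364) did not pass. Among their members with the smallest p, Gpr17 differed by -0.37 (SE 0.108) and Olig2 by 0.36 (SE 0.108) in precursors, Ppp1r3c by -0.37 (SE 0.120) and Gjb6 by 0.32 (SE 0.15) in astrocytes, the lysosomal genes Cd68 and Ctss by -0.44 (SE 0.130) and -0.38 (SE 0.118) in microglia, and Pdgfrb and Tek by 0.37 (SE 0.139) and 0.37 (SE 0.162) in vessels. Tek differed by 0.19 without heterozygous replicate 4, and a second, dim Cd68 probe measured 0.07 (SE 0.142). Blood cell markers had a negative difference in 14 of 15 members, with a median of -0.20 (adjusted p = 0.0536), Alas2, a heme synthesis gene, at -0.49 (SE 0.187) and the globin gene Hbb-bs at -0.86 (SE 0.349), or -0.31 and -0.56 without heterozygous replicate 4. Progenitor and migrating neuroblast markers had a median of 0.01 (adjusted p = 0.96); Hes5 at -0.62 (SE 0.138) and Stmn1 at 0.63 (SE 0.164) passed when adjusted over that list alone.

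Lists of genes tied to the function or position of Brd2, and of general cell functions, missed the threshold. Bromodomain proteins and P-TEFb had a median of 0.01 over 27 members (adjusted p = 0.96); Smarca4, a chromatin remodeller gene, differed by -0.31 (SE 0.110) at its brightest probe and by 0.30 over the mean of its probes, and Hexim2, which encodes an inhibitor of P-TEFb, differed by -0.53 (SE 0.236), with heterozygous values of 14.84 in the library labelled replicate 3 and 16.02 in replicate 4, differences of -0.12 and -0.94 where only the latter or only the former is kept, and further, dim probes at 0.05 (SE 0.109) and 0.08 (SE 0.094). Cell cycle and E2F targets had a median of -0.02 (adjusted p = 0.96), with the cyclin gene Ccne1 at 0.44 (SE 0.157), or 0.29 without the library labelled heterozygous replicate 3. Genes next to Brd2 on chromosome 17 had a median of 0.06 (adjusted p = 0.251), with Atf6b at 0.77 (SE 0.278) and Egfl8 at -0.30 (SE 0.122); the list passed without heterozygous replicate 1 (median 0.10, adjusted p = 0.0122) and with the cortical covariate. Immediate-early genes had a median of -0.05, with Ier5 at -0.61 (SE 0.162), its second probe at 0.055 (SE 0.193), and Bdnf at 0.57 (SE 0.220) (list adjusted p = 0.96). Interferon and inflammatory genes had a median of 0.11 (adjusted p = 0.143), and the list passed with a higher level in 4 of 28 alternatives. Oas2 differed by -0.39 (SE 0.125) and Oas1a by -0.22 (SE 0.105), each well above background in 2 samples per genotype. A second, dim Oas1a probe measured 0.09 (SE 0.098). Oxidative phosphorylation had a median of 0.04 (adjusted p = 0.385), which ranged from -0.21 to 0.19 over the alternatives, with Cox5a at 0.31 (SE 0.102) and Uqcrc1 at 0.33 (SE 0.109); the list was lower with the value table (adjusted p = 0.000819) and higher in the Cy3 samples alone (adjusted p = 0.035) and with the cortical covariate (adjusted p = 0.00461). Cytosolic ribosomal proteins had a median of -0.04 (adjusted p = 0.671), which ranged from -0.32 to 0.07 over the alternatives; the list was lower with the value table (adjusted p = 7.35e-11) and with 75th percentile scaling (adjusted p = 1.71e-06). Rpl13 differed by 0.43 (SE 0.170), but by -0.18 with the processed signals, by 0.27 without wildtype replicate 4 and by -0.35 (SE 0.114) at another bright probe, and Rpl17 by -0.26 (SE 0.095), but by 0.11 with the processed signals.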

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

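Of the tests below, those of tissue from neighbouring regions were chosen only after the result was seen. A sample was singled out when its gap to the nearest of the other 3 samples of its genotype took up most of the group's range. Of 210 groups examined 9 met this, where about 10 would be expected by chance (1 in 20).

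The library labelled heterozygous replicate 3 accounted for 2 of these. It scored 60.7 on the first principal component, where the other heterozygous samples scored -24.2 to -10.6, and its mean correlation with the other 7 samples was 0.96, against 0.98 for the others. Weak signal is argued against: among the brightest genes its spread from the other samples was 1.69 times that of the most variable other Cy3 sample. Tissue from neighbouring regions is a candidate explanation that the lists go with: its median deviation from the other heterozygous samples was 0.60 for markers of the thalamus, septum, pallidum and hypothalamus and 0.62 for choroid, ependymal and meningeal markers, both at percentile 100 of random lists of matched level. That percentile is not particular to such tissue. Oligodendrocyte markers (0.53) and oxidative phosphorylation (0.31) also reached 100, and ribosomal proteins (0.17) reached 99.8. Striatal projection neuron markers (-0.57) lay at percentile 0. In that library Hcrt measured 13.16, Avp 11.36, Prkcd 12.32 and Ttr 16.29. The other 7 samples measured 7.90 to 9.60, 7.32 to 8.48, 9.12 to 9.72 and 11.52 to 14.15. Hcrt, Avp and Prkcd were picked after their values were seen. However, 15 of the 24 neighbouring-region genes and 18 of the 27 choroid genes were also well above background in every wildtype sample, and 11 and 2 of them stand in another list. A wildtype library under this label stays open, given its Brd2 level: over the 100 genes that best separated the other 7 samples it lay nearer the heterozygous mean for 38%, against 29%, 56%, 50% and 14% for wildtype replicates 1 to 4 and 51%, 56% and 42% for heterozygous replicates 1, 2 and 4, so the measure set apart wildtype replicates 1 and 4 but not the other samples of known label.

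The remaining values are given without explanation. After removing the dye effect, Adgra1 measured 9.65 in wildtype replicate 2 and 9.09 to 9.14 in the other wildtype samples. Slc17a7 measured 12.49 in heterozygous replicate 1 and 10.73 to 11.03 in the others of that genotype. Ppp1r3c measured 11.33 in wildtype replicate 3 and 11.50 to 11.52 in the others. Drd2 measured 9.81 in wildtype replicate 2 and 10.13 to 10.16 in the others. Relative to the wildtype mean, the immediate-early gene list stood at 0.26 in heterozygous replicate 1 and -0.07 to -0.02 in the others. Cytosolic ribosomal proteins stood at 0.04 in wildtype replicate 4 and -0.02 to -0.01 in the others. Cortical excitatory markers stood at 0.29 in wildtype replicate 2 and -0.10 to -0.06 in the others.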

How the results depend on the processing

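The settings with a cortical covariate, outlier spots kept, permuted list levels, and the list tests without heterozygous replicate 3 with an estimated correlation were chosen after seeing the data. The count of 0 genes held in limma in 24 of 27 alternatives, every sample left out included. It was 1 with every probe tested separately (Btbd9, 1.82 at a second probe and 0.02 at its brightest), 1 in the Cy5 samples alone (Sv2c, -3.50), and 433 at an unadjusted p under 0.05 with at least a 1.5-fold change. The 1726 genes at unadjusted p under 0.05 became 971 with the value table, 955 with probes well above background in all 8 samples (fewer genes tested), 622 in the Cy3 samples alone (1928 in the Cy5 samples alone), 3056 with the cortical marker level as a covariate, and 799 (without heterozygous replicate 4) to 2336 (without heterozygous replicate 1) with 1 sample left out. Brd2 kept its direction and missed the threshold in all 26 alternatives (-1.08 to -0.28, adjusted p 0.275 to 0.968).

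The 3 lists past the threshold became 7 with processed signals under either scaling, 6 with the value table, 8 with the 2 channels of each array averaged, 1 without the dye covariate, 5 in the Cy3 and 5 in the Cy5 samples alone, 11 with the cortical covariate, and 1 (without wildtype replicate 4) to 11 (without heterozygous replicate 1) with 1 sample left out. They became 0 with an estimated correlation, 0 by fry, 0 by exact permutation of list levels and 0 with an estimated correlation without heterozygous replicate 3. The permutation count decides little: the smallest p that this test can give is 0.0286. After adjustment over 27 lists that p passes only if many lists reach it at once. The cortical list turned to -0.22 with its own level as a covariate, as that construction implies. With probes well above background in all 8 samples the count is 3 again, but with other lists: striatal projection neuron, dopamine and blood cell lists passed, and the cortical (adjusted p = 0.601) and vesicle (adjusted p = 0.0741) calls were lost. Apart from the turn of the cortical list, the cause of these changes was not tested. Among the other named genes 2044 values kept their sign and side of the threshold and 13 changed sign: Gad1 at -0.04 and -0.17 with processed signals (Aquantile and 75th percentile), -0.15 with the value table, -0.20 in Cy3, -0.30 with the cortical covariate and -0.17 to 0.37 with 1 sample left out; Rpl13 at -0.18 and -0.37 and Rpl17 at 0.11 with processed signals; Smarca4 at 0.30 as the mean of its probes; and Drd2 at -0.60 to 0.02 with 1 sample left out. No scaling moved the median over all genes beyond -0.06.

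Without the array block 1746 genes had an unadjusted p under 0.05, against 1726 with it. The array correlation was 0.0076 in the main fit, -0.32 with the cortical covariate and 0.5 without heterozygous replicate 4. With replicate number as a block there were 0 genes past the threshold, 2042 at unadjusted p under 0.05 and 5 lists. The numbers share a dye and do not pair the samples: the deviations of same-numbered samples correlated at 0.116, 0.198, 0.210 and 0.183, but once the dye was removed at 0.164, -0.290, -0.185 and -0.251, and 0 of 4 correlated best with their own number. Signal over background limits Cy3 most, where 37.7% to 47.6% of spots were well above it. In Cy5 this share went with genotype, at 65.9% and 68.9% in wildtype and 74.7% and 75.5% in heterozygous samples. Median Cy5 spot intensity was 211.9 and 235 in wildtype and 359.3 and 321.3 in heterozygous samples. Each array held 1 genotype, so this cannot be told apart from genotype. Its part in the differences of dim genes was not tested.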

Other observations

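Of the tests below, those of cortical tissue share, of Cy3 signal, of Ido1 without heterozygous replicate 3, and the count of splits for genes past the threshold were chosen only after the result was seen.

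The genes and the list in this paragraph were chosen after their values were seen. The values of Sv2c, a synaptic vesicle gene, lay further apart between genotypes in Cy5 than in Cy3, and no sample was measured in both dyes. It measured 10.61 and 10.68 in the wildtype and 7.19 and 7.11 in the heterozygous Cy5 samples, but 10.84 and 10.71 against 10.32 and 10.37 in Cy3. Blood cell markers missed the threshold as a list but passed it, with a lower level in heterozygous samples, in 11 of 28 alternatives (adjusted p 0.00267 to 0.875). Their level relative to the wildtype mean was -0.16, -0.05, -0.35 and -0.49 in heterozygous replicates 1 to 4, and the globin gene Hbb-bt differed by -0.75 (SE 0.299).

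Splits of the same 8 samples into 4 and 4 set these counts against chance; 34 could be fitted, since 1 follows the dye. For genes past the threshold the real count is 0, so all 34 necessarily give as many, which says nothing about chance; the highest other split gave 0. For unadjusted p under 0.05, 7 of the 34 gave at least the real 1726, the highest other 2767, so chance cannot be excluded. The other splits that keep arrays whole gave 1019 and 655 such genes. For gene lists past the threshold, 25 of the 34 gave at least the real 3, the highest other 14, so chance cannot be excluded there either. That split sets replicates 1 and 2 of both genotypes against replicates 3 and 4 and keeps arrays whole, and gave 655 genes at unadjusted p under 0.05.

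The higher level of cortical excitatory markers in heterozygous samples may reflect an unequal share of cortical tissue between samples. After removing genotype and dye the members still moved together, with a mean pairwise correlation of 0.20 against a median of -0.006 in random lists of matched level, of which 1 in 20 exceeded 0.063. Random genes are a weak comparison for a list of related genes. The inter-gene correlation estimated in camera was 0.203 here, but 0.236 for oxidative phosphorylation and 0.246 for interferon genes. It was lower for others, such as 0.0168 for GABA signalling. Moving together therefore does not single out cortical tissue share. Of the 28 tested members 19 were also well above background in every wildtype sample, and 2 stand in another list. Loss of signal near background in Cy3 cannot be told apart as a contributor: the median difference was 0.17 in the Cy5 samples alone, where the list passed (adjusted p = 0.036, with 0.000138 to 0.875 over all alternatives), but these are 4 samples and the lower heterozygous list level, 0.11, lay below the higher wildtype one, 0.29; with probes well above background in all samples it was -0.02 (adjusted p = 0.601), a filter that removes members low in wildtype and so decides nothing. An effect of genotype stays open and was not tested apart from these.

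For Ido1, lower in 4 of 4 heterozygous samples, a smaller share of striatal projection neurons is argued against as the whole cause. With the mean level of the other projection neuron markers as a covariate the difference was -1.11 (SE 0.11), against -1.15 (SE 0.110) without it. Without the library labelled heterozygous replicate 3 it was -1.12, so that library is not its source. An effect of Brd2 dosage on Ido1 stays a hypothesis: Ido1 missed the threshold in the full comparison (adjusted p = 0.133, with 0.0781 to 0.968 over the alternatives), and probe-specific effects were not tested.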
